A study of Mus musculus with 7 samples.

How the data were processed

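RNA from neocortex of 7 mouse samples was sequenced after TRIzol extraction and strand-specific Illumina TruSeq library preparation with USER treatment, per the labels' protocols. Reads were aligned with STAR to the mouse genome GRCm38 (mm10), per the submitters' processing notes, which name no version. How inclusion was computed from the alignments is not given in the sources used here. Whether a library holds tissue of 1 animal or of several is not stated in the labels.

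The values used were inclusion ratios, which are deposited as a fraction between 0 and 1 per exon and library, per the file headers. They were multiplied to percent. Differences between ratios are also deposited per the file headers, and they equal the differences recomputed from the ratios (largest gap 0 percentage points at the 6 decimals given). A p-value for wildtype against knockout and for knock-in against knockout stands beside each exon in the authors' deposited table. The test behind the p-values, and whether they were adjusted, is not given in the sources used here. 16 p-values were missing and 42 were exactly 0, of which 37 belonged to exons with a ratio of 0 or 100% in at least 1 library.

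From the values, the exons that changed in the knockout moved by at least 10 points with p up to 0.0496 in the authors' deposited table, and those that changed in the knock-in by at least 10 points with p up to 0.0498. Exons listed under PTBP2 alone moved by at most 9.97 points in the knock-in, and those listed under PTBP1 alone by at most 9.87 points in the knockout. In the table of exons inhibited by both proteins the 2 p-value columns appear exchanged, so no p-value of single exons from it is printed; every p-value in it passes the threshold, and class membership does not depend on the order. No read counts or depths were used, so no interval covers the error of a single level. The column headed DM was matched to Emx1-Ptbp2KO-Ptbp1KI, the only P1 genotype left after the wildtype and the knockout.

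The samples form 7 groups of 1 library: E14, E17, P2 and P10 in BL6, and wildtype, Emx1-Ptbp2KO and Emx1-Ptbp2KO-Ptbp1KI at P1 in 129/BL6. No test compares libraries. Recovery by the knock-in was (knock-in minus knockout) over (wildtype minus knockout) per exon, in percent. Medians over exons carry 95% binomial order-statistic intervals and shares carry 95% Clopper-Pearson intervals; both treat exons as independent, and 33 listed exons overlap another listed exon. Correlations and median lengths were tested with 100000 permutations and shares with Fisher's exact test, all two-sided and across exons. Expression of Ptbp1 and Ptbp2 themselves, cell type markers and other clusters of exons are not analysed here.

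Exon coordinates are 1-based on GRCm38 as in the files. They were set beside GENCODE M21, in which 609 of the 611 exons have an annotated exon with the same ends, 588 of them in a gene of the same symbol. An exon was called coding where a matching exon of a protein-coding transcript lies within the coding sequence. On the opposite strand, 33 exons overlap another gene, and on the same strand 37 do; inclusion there may mix transcripts where strand was not used in the counting, which is not stated. The intervening sequences around the exons were not analysed here.

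Exons were named by a rule fixed before the data were examined: Ptbp1, Ptbp2 and Ptbp3 wherever listed, the 5 exons of each class with the largest absolute knockout change, and up to 4 exons per class from each of 9 fixed gene lists with 206 different genes. Further list members are named without values, and some exons that the rule names are not reported here. The lists were PTB proteins, known PTB targets, axon growth and guidance, microtubule and motor, actin and adhesion, synapse and ion channels, vesicle traffic, RNA binding and splicing, and chromatin and transcription. Alternatives fixed at the same time were 1 exon per gene, a minimum change of 20 points, means, recovery from class medians, other ages, Spearman's rho, a length limit of 150 nt and genes counted once per direction. Added after the data were examined were counts without exons at 0 or 100%, recovery in exons with a deposited p below 1e-20 (without those at 0 or 100% in wildtype or knockout), recovery over all exons of a direction that changed in the knockout, the share responding to both proteins with 1 exon per gene, ages without clusters 5 and 6, and length in the PTBP2-only classes.

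The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were first tested on simulated data: in 357 simulated exons with a true recovery of 30% the median recovered was 29.3%, and the comparison of p-values with changes gave 100% before and 0% after the columns were exchanged. Depth was equal in that simulation and the knockout change was much the larger. It therefore does not cover exons whose 2 changes are similar in size. Of 100 simulated relations over 238 exons with no effect, 2 had a permutation p below the 0.05 threshold, and the order-statistic interval held the true median in 98% of simulated sets.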

Results

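Exon inclusion was compared in 7 RNA sequencing libraries of mouse neocortex. 4 libraries were from BL6 mice at embryonic days 14 and 17 (E14 and E17) and postnatal days 2 and 10 (P2 and P10). The other 3 were from 129/BL6 mice at postnatal day 1 (P1): wildtype, Emx1-Ptbp2KO (a Ptbp2 knockout) and Emx1-Ptbp2KO-Ptbp1KI (the same knockout with a Ptbp1 knock-in), named here wildtype, knockout and knock-in. PTBP1 and PTBP2 are related RNA-binding proteins that regulate splicing; PTBP1 is found in neural progenitors and PTBP2 in differentiating neurons. Emx1 is a gene of the dorsal forebrain lineage. The value per exon and library was the inclusion level, the percentage of transcripts that contain the exon. Each age and each genotype had 1 library, so no difference between libraries had a replicate check, and tests across exons describe these libraries only. Age and strain differed between the 2 sets of libraries, and the read depth behind each level is unknown.

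The genotype tables listed 611 exons of 538 gene symbols, sorted by the authors into 6 classes. A class states whether an exon was activated (lower inclusion without the protein) or inhibited (higher inclusion without it), and whether it responded to PTBP2, to PTBP1 or to both. Listed exons changed by at least 10 percentage points, with p-values of up to 0.0498 in the authors' deposited table. The third genotype is headed DM there and was taken as the knock-in, the only P1 library left to match.

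The question of the knockout comparison was which exons depend on PTBP2 in the newborn neocortex. Loss of Ptbp2 mostly raised inclusion: 418 of the 520 exons that changed in the knockout were higher than in wildtype (80.4%, 95% Clopper-Pearson interval over exons 76.7 to 83.7), and 102 were lower. The largest class, exons inhibited by PTBP2 alone, held 357 exons of 315 genes, whose median inclusion was 51.2% in wildtype and 70.0% in the knockout. The median rise per exon was 14.2 percentage points (95% order-statistic interval 13.3 to 15.1), and 91 exons rose by at least 20. In the 61 exons inhibited by both proteins the median level was 36.4% in wildtype and 60.2% in the knockout, with a median rise of 16.8 points (14.5 to 20.4).

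The widest gap was in Sympk, which encodes a scaffold protein of mRNA 3' end processing. Its 126-nt exon (GRCm38 chromosome 7, 19027897 to 19028022, in an untranslated region of annotated protein-coding transcripts) was at 0.220% in wildtype and 71.5% in the knockout. A 79-nt non-coding exon of 4930513N10Rik went from 18.9% to 80.0%, but an annotated gene lies on the opposite strand there. A 72-nt exon of the zinc finger gene Ikzf4, annotated in transcripts subject to nonsense-mediated decay (NMD), went from 9.68% to 58.3%. An 84-nt coding exon of Scrib, a cell polarity gene (chromosome 15, 76049457 to 76049540), rose from 33.0% to 75.2%, and a 99-nt exon of the formin Fmnl1 from 46.3% to 88.2%. Among exons inhibited by both proteins, a 138-nt exon of Slc4a10, a bicarbonate transporter (chromosome 2, 62265042 to 62265179, in a non-coding transcript), went from 9.96% to 72.4%. An exon of Stam2 in an NMD transcript went from 4.96% to 60.2%.

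Synapse and ion channel genes, the largest of the 9 gene lists with 40 genes, held 15 listed exons of 13 genes, 13 inhibited by PTBP2 and 2 activated. Camk2b, the beta subunit of calcium/calmodulin-dependent kinase II, had 2 such exons. Its 75-nt coding exon (chromosome 11, 5987057 to 5987131) rose from 60.8% to 93.4% and its 45-nt coding exon (5981070 to 5981114) from 78.0% to 98.4%. A coding exon of the scaffold gene Magi1 rose from 36.0% to 71.8%. Coding exons of Scn8a, Grin1, Shank3, Camk2d, Nrxn2 and Rims1 and an exon of Nlgn3 were also in this class.

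Genes of the cytoskeleton and of vesicle traffic were mostly on the inhibited side as well. In this they and the synapse genes followed listed exons as a whole. Of all 611 listed exons 465 were inhibited, and of those of PTBP2 alone 82.1%. No gene list stood out in the test given under the other observations. Of the 8 microtubule and motor exons, 7 were inhibited by PTBP2, among them 2 coding exons of the kinesin Kif21a, at 15.4% and 42.2% in wildtype and 39.8% and 71.1% in the knockout. The 24-nt exon of the axonal kinesin Kif1a went from 29.9% to 47.3%. All 5 actin and adhesion exons were inhibited, such as the 12-nt coding exon of the actin regulator Enah (18.7% to 39.4%) and a 27-nt exon of the ankyrin gene Ank3 (54.4% to 71.0%). Of the 7 axon growth and guidance exons, 6 were inhibited, among them an 801-nt exon of the adhesion molecule gene Ncam1, which rose by 21.8 points from 50.2%, and 2 exons of the ephrin receptor Epha5. Of 15 vesicle traffic genes, 5 had a listed exon each, 4 of them inhibited; the 30-nt coding exon of the membrane fission GTPase Dnm2 (chromosome 9, 21487047 to 21487076) went from 7.80% to 49.5%, and exons of Exoc7, Cltb and Ap2a1 rose by 25.2, 23.9 and 17.1 points.

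RNA-binding and chromatin genes gave 4 listed exons each, from lists of 29 and 24 genes. For the translational repressor Pum2, 2 exons annotated in NMD transcripts went from 13.2% to 42.7% and from 11.1% to 46.4%. A coding exon of Fxr1 went from 38.3% to 49.1%, with an annotated gene on the opposite strand. The chromatin remodelling gene Smarcc2 had a coding exon at 41.8% in wildtype and 71.4% in the knockout, and exons of Kmt2c and Ehmt2 rose by 16.7 and 10.7 points. Of 26 genes fixed beforehand as known PTB targets, 7 had 9 listed exons, of which 7 were inhibited.

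**Figure D1:**
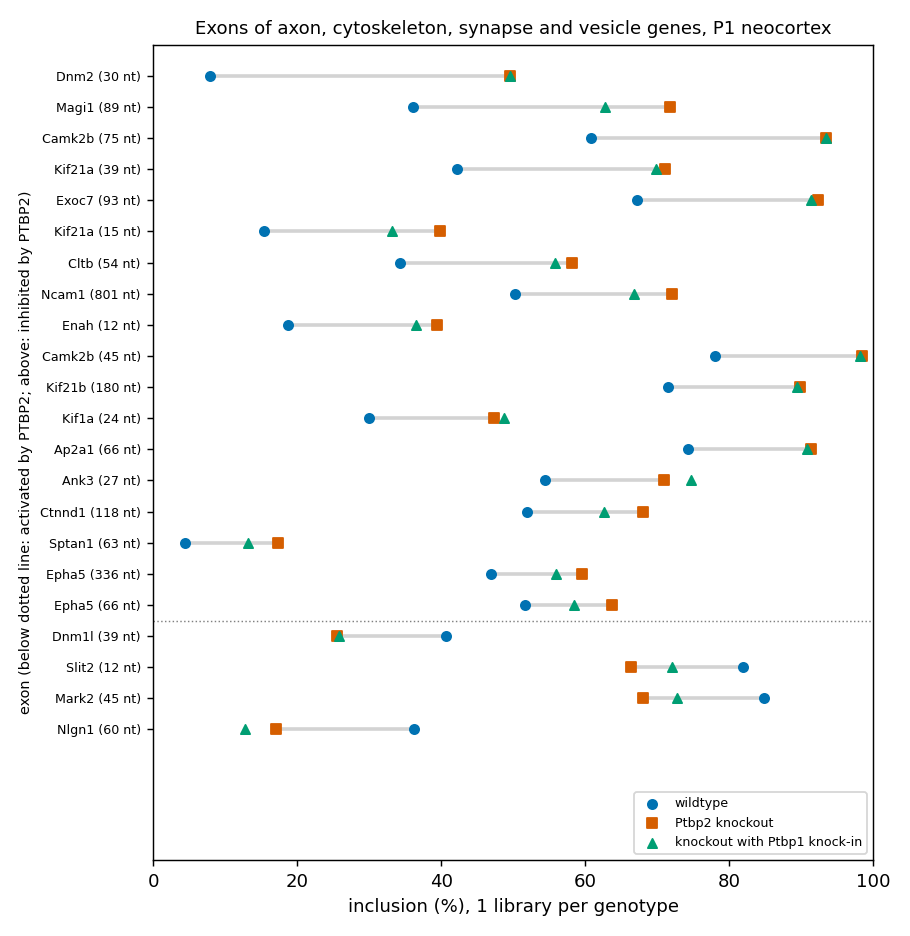
Inclusion in percent (horizontal axis) of 22 exons of axon, cytoskeleton, synapse and vesicle genes at P1 in the wildtype (circles), knockout (squares) and knock-in (triangles) libraries, 1 library each, with a grey line from wildtype to knockout. The 18 exons inhibited by PTBP2 lie to the right of wildtype in the knockout and the 4 activated exons to the left, and the 30-nt Dnm2 exon is at 49.5% in both the knockout and the knock-in.

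Exons with lower inclusion in the knockout were fewer. The 78 exons activated by PTBP2 alone had a median inclusion of 58.3% in wildtype and 41.6% in the knockout, and the median change was -14.3 points (-15.7 to -12.6). The 24 exons activated by both proteins went from 66.1% to 43.1%, with a median change of -17.2 points (-28.9 to -14.5). Among exons activated by PTBP2 alone, a 91-nt coding exon was among the 5 largest changes in each of 2 CDC-like kinases, which phosphorylate SR splicing factors. The Clk1 exon (chromosome 1, 58420121 to 58420211) was at 93.6% in wildtype and 55.6% in the knockout, and the Clk4 exon (chromosome 11, 51273078 to 51273168) at 70.4% and 37.7%. Coding exons of Sytl2, a Rab27 effector, and Abi2, a regulator of actin assembly, fell by 33.4 and 30.4 points. Among listed neuronal genes, exons of Nlgn1, Slit2, Mark2 and the mitochondrial fission gene Dnm1l fell by 19.2, 15.6, 16.8 and 15.2 points, and a coding exon of the Wnt effector Tcf7l2 by 27.6. In the class activated by both, 2 nested exons of the p53 target Aen fell by 54.4 and 51.0 points, and an untranslated exon of Armcx1 by 45.8.

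The knock-in comparison asked which of these exons return when PTBP1 is supplied. How much PTBP1 the knock-in supplies was not analysed here, so a low recovery does not show that PTBP1 cannot regulate an exon. Of the 520 exons that changed in the knockout, 85 also moved back by at least 10 points in the knock-in and were listed under both proteins (16.3%, Clopper-Pearson 13.3 to 19.8). That share was 23.5% (15.7 to 33.0) of the activated and 14.6% (11.4 to 18.3) of the inhibited exons (Fisher's exact test across exons, two-sided p = 0.0361). With 1 exon per gene it was 22 of 95 activated and 56 of 364 inhibited exons, and the difference no longer passed (Fisher's exact test, p = 0.0906). Over all 418 inhibited exons the median inclusion was 49.0% in wildtype, 68.7% in the knockout and 64.5% in the knock-in, and the knock-in recovered a median 17.8% of the change per exon (12.9 to 22.3). Over all 102 activated exons the medians were 61.3%, 41.8% and 50.1%, with a median recovery of 32.7% (22.0 to 38.4). Among the 520 exons none moved further from wildtype by 10 points or more, and the classes leave no place for one. The largest such moves were 9.87 points in exons inhibited and -7.00 points in exons activated by PTBP2 alone. The sorting may therefore raise the recovery over all exons of a direction as well.

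Within single classes the recovery follows from how the exons were sorted, since PTBP2 alone allows a knock-in change of at most 9.97 points and both proteins require at least 10. It was 11.4% (8.22 to 15.03) in exons inhibited and 15.9% (9.28 to 29.1) in exons activated by PTBP2 alone, against 89.3% (85.4 to 100) and 98.5% (85.1 to 124) in those inhibited and activated by both. Among named exons, the Dnm2 exon was at 49.5% in both the knockout and the knock-in, and the Camk2b exons were at 93.5% and 98.1% in the knock-in. The Clk1 exon was at 55.6% in the knockout and 56.2% in the knock-in, and the Sympk exon at 71.5% and 64.1%. Of the exons listed under both proteins, the largest changes often recovered in part: the 2 Aen exons went from 44.3% to 63.9% and from 47.9% to 67.4%, the Slc4a10 exon from 72.4% to 51.7% and the Stam2 exon from 60.2% to 48.0%. The Armcx1 exon went from 30.6% to 76.2%, close to its wildtype level of 76.4%, and an exon of the homeobox gene Prrx1 from 27.8% to 68.8%, above its wildtype level of 60.8%. A coding exon of the growth factor receptor Fgfr2 was at 65.5%, 50.9% and 65.1% in the wildtype, knockout and knock-in. With a change of at least 20 points the median recovery was 69.2% in the 23 exons inhibited by both and 96.4% in the 9 activated by both. A further setting took the 4 exons activated by both with a p below 1e-20 in the authors' deposited table and no level of 0 or 100% in wildtype or knockout. Their median recovery was 47.1%, and 2 of the 4 are the nested Aen exons. The knockout library enters both differences, so its own error also moves exons towards full recovery.

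Exons listed under PTBP1 alone went both ways: 47 inhibited and 44 activated, or 51.6% inhibited (40.9 to 62.3), against 82.1% (78.1 to 85.6) of the 435 exons of PTBP2 alone. The knock-in changed them by a median of -12.0 points (-13.0 to -11.2) and 13.1 points (11.9 to 14.6). In the knockout they had moved by less than 10 points, with medians of 4.88 (3.26 to 6.67) and -3.74 (-5.22 to -2.58). In the knock-in 38 of the 47 and 35 of the 44 moved towards wildtype, and the knockout library enters both changes. The class name therefore does not show that PTBP2 has no effect on these exons. A 34-nt coding exon of Ptbp3, the remaining PTB paralogue (chromosome 4, 59546149 to 59546182), was at 23.0% in wildtype, 30.2% in the knockout and 44.4% in the knock-in. An exon of the splicing gene Son in an NMD transcript was at 28.0%, 37.7% and 24.6%, a coding exon of the splicing regulator Rbm5 at 89.8%, 80.1% and 68.7%, and an untranslated exon of the chromatin gene Hmga1 at 17.3%, 8.20% and 19.9%. A 1049-nt exon of the splicing factor gene Mbnl1 was at 96.1%, 100% and 86.7%.

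**Figure D2:**
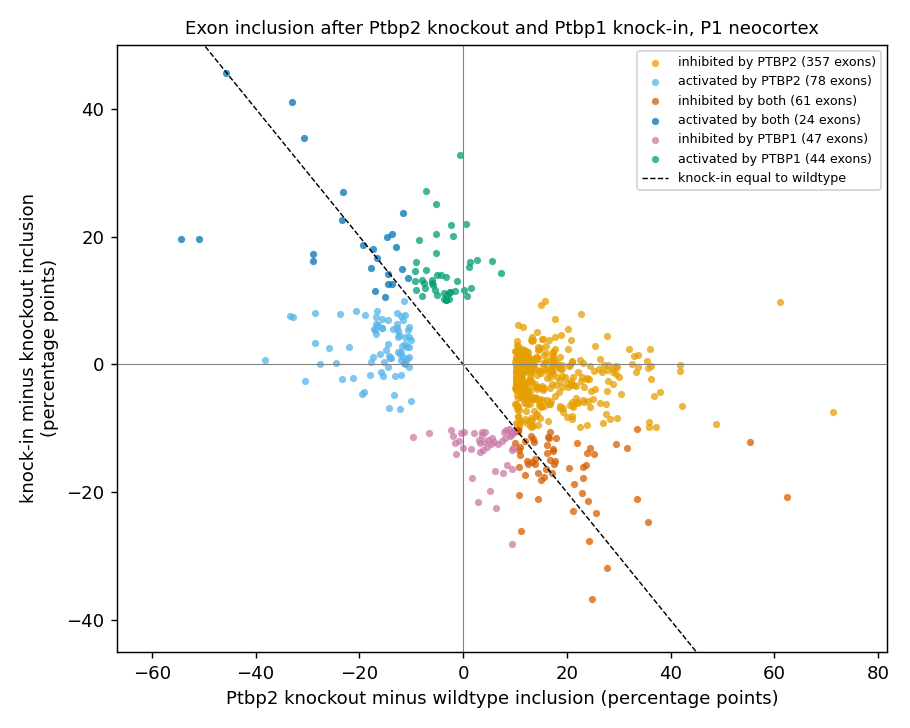
Knock-in minus knockout inclusion (vertical axis, percentage points) against knockout minus wildtype inclusion (horizontal axis, percentage points) for 611 exons, 1 point per exon, coloured by the authors' class. Points on the dashed line are at the same level in knock-in and wildtype. The 357 exons inhibited by PTBP2 alone lie within 10 points of the horizontal zero line, as the class requires. Their median knock-in change is -1.87 points, and 257 of them moved towards wildtype.

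The age comparison asked how PTB-regulated exons change as the neocortex develops. Levels at 4 ages were used for 268 exons in 7 clusters numbered by the authors: 238 of the 357 exons inhibited by PTBP2 alone, 10 of the 61 inhibited by both and 20 of the 78 activated by PTBP2 alone. The others are not analysed here, so the values describe these clusters and not whole classes. The 238 exons inhibited by PTBP2 mostly gained inclusion with age, and their median was 18.9% at E14, 35.6% at E17, 53.2% at P2 and 58.1% at P10. P10 was above E14 in 218 of them (91.6%, Clopper-Pearson 87.3 to 94.8), with a median rise of 32.4 points (26.2 to 36.4). All 20 exons of the activated clusters were lower at P10 than at E14; their median went from 71.6% to 31.8%, with a median change of -37.7 points (-47.8 to -20.8). All 10 exons inhibited by both proteins were higher at P10 than at E14, but their median was 57.8% at P2 and 42.4% at P10. The clusters are the study's own and separate exons by these levels, so the shared directions are not independent evidence.

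The steepest rise was in the 75 exons of repressed cluster 3, by a median of 52.7 points. This cluster held the exons of Magi1 (1.57% at E14 and 87.7% at P10), Camk2b (75 nt, 17.8% and 92.6%), Kif21b (10.2% and 91.2%), Epha5 (66 nt, 5.17% and 73.2%), Cltb (12.1% and 77.0%) and Enah (2.13% and 47.2%). The 59 exons of cluster 2 began higher and rose by 33.4 points. The 52 exons of cluster 5 had a median rise of 11.4 points, and 14 of them were lower at P10 than at E14, such as the Ank3 exon (46.1% and 20.6%). The 52 exons of cluster 6 had the lowest medians, 4.37% at E14 and 13.1% at P10, although single exons were higher, such as the 15-nt exon of Kif21a at 45.8% at P10. The cluster included the exons of Dnm2 (0.685% and 6.98%), Sptan1 (0.293% and 2.004%) and Ikzf4 (72 nt, 4.07% and 9.55%). In the activated cluster 2 the Clk4 exon was at 68.0% at E14 and 47.2% at P10.

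Set beside the ages, the P1 wildtype had a median of 41.4% in the 238 exons inhibited by PTBP2, the knockout 62.7% and the knock-in 60.6%. The knockout was above P10 in 149 exons (62.6%, 56.1 to 68.8). By cluster this held in 34 of 59 exons of cluster 2, 37 of 75 of cluster 3 (49.3%, 37.6 to 61.1), 32 of 52 of cluster 5 and 46 of 52 of cluster 6 (88.5%, 76.6 to 95.6). All 238 exons were chosen for a knockout rise, so these counts are not independent of that choice. Cluster 6 is also low at most ages. The wildtype was above P10 in 21 of 52 exons of cluster 6 and 19 of 52 of cluster 5. In clusters 2 and 3 this held in 4 of 59 and 8 of 75. Of the 20 activated exons, 9 were above P10 in the knockout. No relation between the size of the change with age and the size of the knockout change was detected across exons. These exons were all chosen for a knockout change of at least 10 points and for their clusters. Such a choice narrows the range of both changes and can hide a relation. In the 238 exons Pearson's r was 0.00603 (permutation p = 0.927, two-sided) and Spearman's rho 0.0419 (permutation p = 0.519), and r was 0.0237 without the 2 most extreme exons. In the 20 activated exons r was -0.200 (permutation p = 0.412) and -0.167 without the 2 most extreme. In the 10 exons inhibited by both r was 0.218 (permutation p = 0.541) and 0.640 without the 2 most extreme, so its value there rests on single exons. After Benjamini-Hochberg adjustment over these 3 relations the p-values of r were 0.927, 0.812 and 0.812; exons are not independent replicates.

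**Figure D3:**
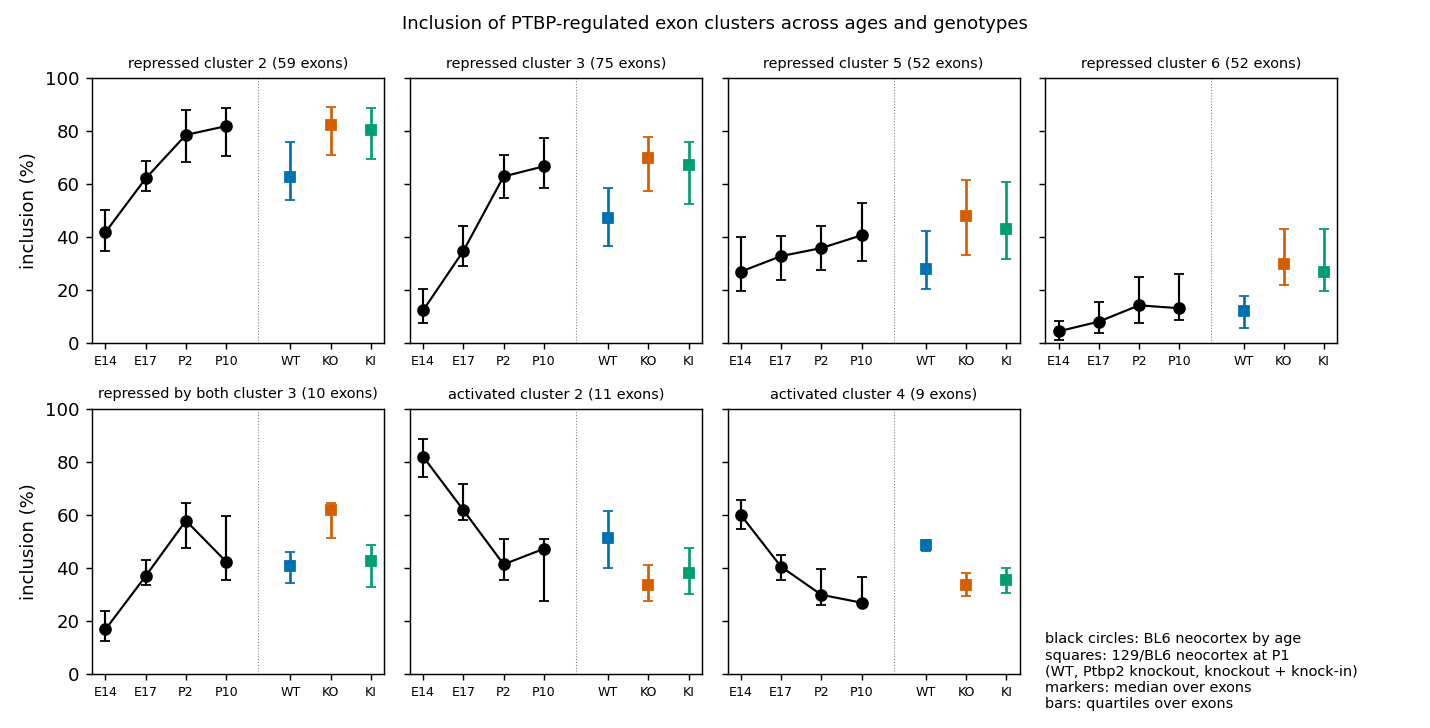
Inclusion in percent (vertical axes) for 7 clusters of exons at E14, E17, P2 and P10 in BL6 neocortex (black circles) and in P1 wildtype, knockout and knock-in neocortex of 129/BL6 mice (coloured squares), as the median over exons with bars for the quartiles. In repressed cluster 6 the median is 13.1% at P10 and 29.8% in the P1 knockout, and in activated cluster 2 it falls from 82.0% at E14 to 33.3% in the knockout.

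Coding exons inhibited by PTBP2 alone had a lower median length than internal coding exons of the annotation and more often had a length divisible by 3. The 247 such exons had a median length of 82 nt (75 to 89), and 189 were divisible by 3 (76.5%, 70.7 to 81.7), against 123 nt and 41.1% for 165262 internal coding exons of the mouse annotation. With the exons that are not fully coding, the class had a median of 85 nt and 64.1% divisible by 3. The 44 exons activated by PTBP1 alone were shorter, with a median of 71.5 nt. Coding exons of the other classes also had medians below 123 nt and shares above 41.1%. These were 102 nt and 65.5% in exons activated by PTBP2 alone and 72 nt and 64.0% in those activated by PTBP1 alone. Those inhibited by both had 90 nt and 61.5%, and those inhibited by PTBP1 alone 121 nt and 48.0%. The 14 activated by both had 88.5 nt and 42.9%. For the share, the interval lay above 41.1% in exons activated by PTBP2 alone (51.4 to 77.8) and by PTBP1 alone (42.5 to 82.0). It included 41.1% in those inhibited by both (40.6 to 79.8), inhibited by PTBP1 alone (27.8 to 68.7) and activated by both (17.7 to 71.1). A higher share than in the annotation was thus not limited to PTBP2 inhibition. Among inhibited coding exons the share was higher under PTBP2 alone, as tested under the other observations. The annotation set was not restricted to variable exons. The comparison of all inhibited with all activated exons gave medians of 93 and 89.5 nt, a difference of 3.5 nt (permutation p = 0.608, two-sided). At most 150 nt long were 80.4% of inhibited and 75.3% of activated exons, a difference of 5.09 points (Fisher's exact test, p = 0.199). Lengths divisible by 3 made up 58.9% of inhibited and 48.6% of activated exons (Fisher's exact test, two-sided p = 0.0351). With 1 exon per gene the frame difference was 8.86 points (Fisher's exact test, p = 0.0735), and within the PTBP2-only classes inhibited exons had a median length that differed from that of activated exons by -28 nt (permutation p = 0.00058).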

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

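Of 82 results recomputed under another setting, 58 were unchanged, 20 moved, 2 lost their call and 2 changed direction. For a test, unchanged meant the same direction and call, and for a median a value within its interval. For a count it meant a value within a fixed ratio of the main count. The settings without exons at 0 or 100%, with a deposited p below 1e-20, without clusters 5 and 6, and within the PTBP2-only classes, and the recovery over all exons of a direction, were chosen after the data were seen. With a minimum change of 20 points, the counts were 91 exons inhibited by PTBP2, 23 inhibited by both, 3 inhibited by PTBP1, 14 activated by PTBP2, 9 activated by both and 7 activated by PTBP1. The median knockout change was then 25.5 points in exons inhibited by PTBP2, 24.4 in those inhibited by both, -26.7 in those activated by PTBP2 and -30.6 in those activated by both, as the construction of the setting implies. The mean knockout change was 17.03 points in exons inhibited by PTBP2 and -16.0 in those activated by PTBP2. Recovery in exons inhibited by both was 75.9% from class medians and 69.2% with a change of at least 20 points. In exons activated by both it was 96.4% with a change of at least 20 points, within its interval. In the 4 exons activated by both with a deposited p below 1e-20 and no level of 0 or 100% in wildtype or knockout it was 47.1%. Over all activated exons changed in the knockout it was 42.3% from medians. From E17 to P2 the change with age was 11.3 points in exons inhibited by PTBP2 and -15.4 in those activated by it, and from E14 to P2 it was 26.1 in the former, over shorter times; without clusters 5 and 6 it was 47.8. The relation of age and knockout changes in the 10 exons inhibited by both had r = -0.173 from E17 to P2 (permutation p = 0.626). The difference in median length became -28 nt within the PTBP2-only classes (permutation p = 0.00058), and the frame difference was 8.86 points with 1 exon per gene (Fisher's exact test, p = 0.0735). The excess of activated exons in the share responding to both proteins was then 7.77 points (Fisher's exact test, p = 0.0906), a setting also chosen after the data were seen. Where no construction explains a change, the cause was not tested. Leaving out a library was not possible with 1 per group, and the settings for term tables and for minimum read coverage were not run because no table used here holds terms or read counts. Read depth, which is unknown, limits every level of a single exon. No paired analysis was possible because each group has 1 library.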

Other observations

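The tests in this part were chosen after the results were seen, except the gene list test, whose background was changed from all exons tested, a table not used here, to the other listed genes. Of the listed genes, 64 had 2 or more listed exons. Since 33 listed exons overlap another, some of these are entries that differ only in their ends. Exons of both directions were listed in 4 genes. These genes are named here after their values were seen. Clk4 had 2 exons that rose in the knockout, a 67-nt coding exon (17.6% in wildtype and 33.3% in the knockout) and a 59-nt exon in an NMD transcript (16.5% and 26.8%), beside the 91-nt coding exon that fell from 70.4% to 37.7%. Crem, a cAMP-responsive transcription factor, had a 147-nt coding exon at 28.4% and 49.2%, a 189-nt coding exon at 50.5% and 33.3%, and a 36-nt coding exon that the knock-in took from 43.4% to 57.4%. Crtc2, a coactivator of the same pathway, had a 407-nt coding exon at 61.4% and 45.0% and a 67-nt exon in an NMD transcript at 77.5% and 88.4%. Depdc5, a regulator of mTORC1, was the fourth such gene.

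Of the other genes with more than 1 listed exon, 3 are given as examples, also named after their values were seen and not members of a fixed list. Agrn, which organises the neuromuscular synapse, had coding exons of 24 nt (43.8% in wildtype and 66.4% in the knockout) and 33 nt (47.0% and 68.8%), with another entry spanning both. Synj1, a phosphatase of synaptic vesicle recycling, had a 48-nt coding exon at 54.4% and 82.1%, and Sorbs2, an adaptor of the actin cytoskeleton, had 3 coding exons, of which a 57-nt exon went from 55.1% to 76.3%. In the knock-in these exons of Agrn, Synj1 and Sorbs2 were at 63.8%, 65.4%, 86.6% and 74.3%.

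In the table of exons inhibited by both proteins, the larger of an exon's 2 changes had the smaller p-value in 3 of 56 exons (5.36%, 1.12 to 14.9). A shallower wildtype library would do the same to exons activated by both, but there it was 21 of 22 (95.5%, 77.2 to 99.9). A candidate explanation is that the 2 p-value columns of the authors' deposited table were exchanged for this class, and the 5.36% is what an exchange would give. No biological explanation was tested.

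For exons listed under PTBP1 alone, inhibited and activated exons were close to balance, which counting error of single libraries could give. Without 8 exons with a p above 0 and below 1e-6 in the authors' deposited table, the inhibited share was 50.6% (39.4 to 61.8) of 83 exons. A response in both directions could give the same balance. The share therefore does not decide whether counting error accounts for part of this class. Another 8 exons, kept in that share, have a p of exactly 0 and a level of 0 or 100% in the knockout or knock-in, where the p was not used. The 8 left out have p-values that counting error would rarely give if the p-values are calibrated. The test behind them is not given and read depth is unknown, so counting error is not excluded for these exons. They include Hmga1, Son and Rbm5 and, named after their values were seen, Dmwd (10.7 points higher in the knock-in than in the knockout) and Hnrnph2 (43.6% in the knockout and 56.7% in the knock-in). A response to PTBP1 and a knock-in or knockout library that differs as a whole stay open, with 1 library per genotype.

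Some exons that were low at all 4 ages were far higher in the knockout, such as Sympk (13.0% at P10 and 71.5% in the knockout) and Dnm2 (6.98% and 49.5%). Exons that were not low at every age also exceeded P10 in the knockout. A 72-nt coding exon of Mlip, named after its values were seen, was at 24.8% at P10, 59.7% in the P1 wildtype and 76.2% in the knockout, and the 27-nt Ank3 exon was at 20.6%, 54.4% and 71.0%. Strain, age and library all differ between P10 and the P1 genotypes.

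Very short exons were tested as a hypothesis. Of the 357 exons inhibited by PTBP2 alone, 39 were at most 27 nt long (10.9%), against 10 of the 254 other listed exons (3.94%), with Fisher's exact test giving p = 0.00143 and an odds ratio of 2.99; with 1 exon per gene it was 32 of 306 against 10 of 232 (p = 0.00908). Among inhibited coding exons, 189 of 247 under PTBP2 alone had a length divisible by 3 (76.5%), against 28 of 51 in the other inhibited classes (54.9%; Fisher's exact test, p = 0.00293). The share was 61.5% in those inhibited by both and 48.0% in those inhibited by PTBP1 alone. In coding exons activated by PTBP2 alone, by PTBP1 alone and by both it was 65.5%, 64.0% and 42.9%. This frame test was not repeated with 1 exon per gene. The gene lists gave no difference that passed: 0 of 9 lists had an adjusted p below 0.05 when genes of exons inhibited by PTBP2 alone were set against the other listed genes, and 0 passed without adjustment. The lowest p-values in Fisher's exact test were 0.0812 for actin and adhesion and 0.0841 for synapse and ion channels (both 0.378 after Benjamini-Hochberg adjustment). Synapse and ion channel genes were 11 of 319 against 2 of 223.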
